A study of Mus musculus with 10 samples.

How the data were processed

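Whole-brain RNA was measured on Affymetrix whole-transcript arrays, per the labels' protocols, from 200 ng of total RNA per array. The brains came from male C57BL/6J mice at postnatal day 70 whose mothers had drunk 10% ethanol in water, or water alone. There were 2 independent experiments. In experiment 1 each array held the pooled RNA of 3 mice (2 ethanol and 2 control arrays, 12 mice in all), and in experiment 2 that of 2 mice (3 ethanol and 3 control arrays, 12 mice in all). Arrays were assigned to treatment, experiment and replicate number from their titles. The pools hold different mice, but the sources used here do not say whether pools shared litters, so p-values measure the spread between pools.

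The deposited values are log2 expression levels per probe set, 35556 probe sets on each of 10 arrays, with no missing value. Partek 6.6 is named in the submitters' processing notes. The background correction, the normalization and any batch step are not given in the sources used here. The deposited log2 values carry a trace of such a step: for every probe set the mean over the 4 arrays of experiment 1 equalled the mean over the 6 arrays of experiment 2 to within 5.83e-05. A difference between the experiments had therefore been removed per probe set before deposit. Levels cannot be compared between experiments in this table, and the planned comparison of the control groups of the experiments is void and has no value here. Differences between ethanol and control arrays within an experiment are not fixed by that step.

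Probe sets were named through the platform annotation, which listed 23410 of them. Of these, 21789 carried 1 gene symbol (19939 different genes) and were tested, and 1621 carried several symbols and were not named. The other 12146 probe sets were not listed and stayed unnamed. Symbols were checked through Entrez identifiers against the RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols. No genome build is given in the sources used here, so no coordinates are reported.

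Differences were estimated with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings and Benjamini-Hochberg adjustment at 0.05. The comparison over both experiments had terms for experiment and treatment (7 residual degrees of freedom, to which the prior added 5.57). A fit with a mean for each experiment and treatment gave the ethanol difference within each experiment and the difference between those differences (6 residual degrees of freedom). All signed values are ethanol minus control on the log2 scale, or experiment 2 minus experiment 1 for the difference between experiments. Array-level summaries were compared with a two-sided exact permutation test of treatment within experiments, which has 120 assignments and cannot give a p below 0.0167. The agreement of the experiments was measured as the correlation of their ethanol differences across genes. The experiments share no arrays, and genes are not independent replicates, so no p across genes is given.

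Gene lists for brain cell types, brain regions, neurotransmission, neuronal activity and stress, ethanol and epigenetic functions, signalling, and housekeeping functions (36 lists) were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, that with the highest mean. They were tested again with an estimated correlation and with fry. Of 692 genes on the lists and on the checks of sex and reference genes, 615 had a probe set with 1 symbol. The groups, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took, among genes with the same sign in both experiments, up to 12 rises and 12 falls past adjusted p 0.05, filled with the smallest unadjusted p among genes with a change of at least 1.2-fold. Predicted genes, clone names and olfactory and vomeronasal receptors were left out of that filling. It also took the 6 smallest p for the difference between experiments and up to 4 members of each list described, those past the threshold over the list alone first.

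The alternatives were quantile normalization, median centring, filters on dim probe sets at the 25th percentile and at the median, all probe sets, another variance prior, array weights, weights by mice per pool, other experiment terms, a replicate block, each experiment fitted alone, an unmoderated linear model, another threshold, other set tests, and each array left out in turn. The procedure was tested on simulated data made for the comparison over both experiments with 21789 genes. Of 50 genes changed by 0.25 log2 units it called 25, of 50 changed by 0.5 it called 46, of 50 changed by 1 it called 50, and of 50 changed by 2 it called 49. It called 9 of 21589 unchanged genes. In these simulations arrays differed only by noise drawn gene by gene, so shared differences between pools were not part of them. Figures were drawn with matplotlib 3.10.9.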

Results

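The study asked whether exposure to alcohol before and shortly after birth leaves a difference in gene expression in the adult brain. Female C57BL/6J mice drank 10% ethanol or water during pregnancy and until their pups reached postnatal day 10, and whole brains of the male offspring were collected at postnatal day 70. The 10 arrays comprised 2 ethanol and 2 control pools of 3 brains each (experiment 1) and 3 ethanol and 3 control pools of 2 brains each (experiment 2). Deposited log2 values ran from 4.27 to 15.4, the array medians from 6.99 to 7.05, and the correlations between arrays across probe sets from 0.989 to 0.996. The number of arrays limited the precision, with a median standard error of 0.0519 log2 units for an ethanol difference over both experiments.

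The sex-linked transcripts fitted the male label on each array group. Xist, which is transcribed from the inactive X chromosome of female cells, had group means of 5.08 to 5.17 log2 units. The Y-linked genes Kdm5d, Uty and Eif2s3y had group means of 8.84 to 8.89, 9.49 to 9.67 and 10.0 to 10.2. Of 9 common reference genes measured, the differences ran from -0.05 for Sdha to 0.04 for Actb, and none had an unadjusted limma p under 0.05.

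Over both experiments, the largest differences between the ethanol and control arrays were in transcripts of pituitary hormones. Gh, growth hormone, was higher on the ethanol arrays by 2.96 ± 1.03 log2 units (SE), Prl, prolactin, by 2.72 ± 0.87, and Cga, the shared alpha subunit of the glycoprotein hormones, by 1.89 ± 0.67. None of these genes passed adjusted p 0.05 over all genes, and their excess was uneven among the ethanol arrays. The difference in their mean had a two-sided p of 0.0833 by the exact permutation test within experiments. Markers of cerebellar granule and Purkinje cells and of the choroid plexus were lower, with median differences of -0.20 and -0.10 log2 units. Immediate early genes, which neurons transcribe within minutes of activity, were higher by a median of 0.16 log2 units. These 4 were the lists of 36 that passed adjusted p 0.05 by camera, 2 upward and 2 downward. With an estimated correlation 0 lists passed, and fry called 0.

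Of the 12 pituitary and pineal markers measured, 11 were higher on the ethanol arrays, with a median difference of 0.27 (camera adjusted p = 2.5e-05; adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, 5 passed and over all genes 0. These were Gh, Prl, Lhb, the beta subunit of luteinizing hormone (0.28 ± 0.09), Ghrhr, the receptor for growth-hormone-releasing hormone (0.28 ± 0.08), and Cga, which was named after its values were seen. Within the list Pomc (0.41 ± 0.19) and Fshb (0.26 ± 0.11), also named after their values were seen, missed that threshold. The excess of Gh, Prl and Cga lay on 3 of the 5 ethanol arrays. Their mean was 10.7 and 9.08 on the ethanol arrays of experiment 1 against 5.66 and 5.91 on its controls. In experiment 2 it was 11.9 on ethanol replicate 2, while ethanol replicates 1 and 3 had 6.91 and 6.95 and the controls 6.87, 6.78 and 7.69. The difference in this mean was 2.52 log2 units (exact permutation test within experiments, two-sided p = 0.0833, 5 ethanol against 5 control arrays). The list's median difference was 0.41 over the 7 members above the 25th percentile of mean level and 2.84 over the 2 above the median, Gh and Prl. That filter used means over all arrays, and 0 of the 12 members had a control mean above the median of the gene probe sets. Gh and Prl thus passed it only through the arrays where they were high, and the 2.84 follows from that selection. With the mean of Gh, Prl and Cga as a covariate, chosen after seeing the data, the list's median difference was 0.00 (camera adjusted p = 0.523). By construction that covariate sets the mean difference of those 3 genes to 0, though not the median of the list. As they are 3 of its 12 members, the list's median and camera p are also affected by this and carry little weight.

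**Figure D1:**
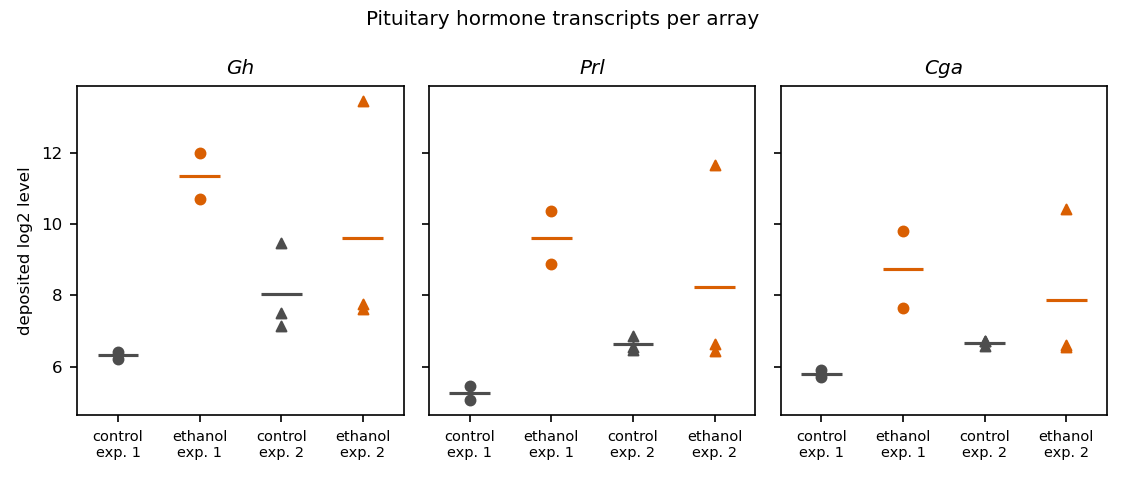
Deposited log2 levels (y axis) of Gh, Prl and Cga on each array, by treatment and experiment (x axis), with a line at each group mean (n = 2 arrays per group in experiment 1 and 3 in experiment 2). Both ethanol arrays of experiment 1 and 1 of the 3 in experiment 2 stand above the controls, and levels are comparable only within an experiment.

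All 14 cerebellar markers measured had lower values on the ethanol arrays (camera adjusted p = 1.1e-05; adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, 2 passed, and over all genes 0. These were Zic2 (-0.22 ± 0.07) and Zic1 (-0.20 ± 0.06), zinc finger transcription factors of cerebellar granule cells. Gabra6, the granule cell GABA receptor subunit (-0.28 ± 0.10), and Car8, a Purkinje cell protein (-0.20 ± 0.08), did not pass. Relative to the control mean of the experiment, the list's median was -0.53 on ethanol replicate 2 and -0.11 on ethanol replicate 1 of experiment 1, and -0.05, 0.00 and -0.31 on ethanol replicates 1, 2 and 3 of experiment 2. Without ethanol replicate 2 of experiment 1 the list's median difference was -0.11 (camera adjusted p = 0.00461), and with array weights it was -0.13 (camera adjusted p = 9.7e-04).

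Of 16 choroid plexus and ependymal markers measured, 15 were lower (camera adjusted p = 3.8e-05; adjusted p = 0.73 with an estimated correlation). The list's median difference was -0.02 in experiment 1 (camera adjusted p = 0.737) and -0.19 in experiment 2 (camera adjusted p = 1.9e-08). Over both experiments, 5 markers passed adjusted over the list alone, and 0 over all genes. They were Kcnj13, a potassium channel of the choroid plexus epithelium (-0.31 ± 0.06), Otx2, a homeobox transcription factor (-0.29 ± 0.06), Kl, which encodes klotho (-0.27 ± 0.06), Lbp, lipopolysaccharide binding protein (-0.21 ± 0.05), and Slc4a5, a bicarbonate transporter (-0.24 ± 0.07), the last named after its values were seen. Ttr, transthyretin, the abundant transcript of this epithelium, differed by -0.11 ± 0.06 and did not pass, and was also named after its values were seen. Without control replicate 2 of experiment 2 the list's median difference was -0.06 (camera adjusted p = 0.00177), and that array also had the highest mean of olfactory mucosa genes in its experiment (8.40). It was -0.20 over the 8 members above the median level, and -0.15 with the mean of Gh, Prl and Cga as a covariate, chosen after seeing the data.

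Of the 25 immediate early genes, 23 were higher (camera adjusted p = 2.4e-04; adjusted p = 0.73 with an estimated correlation), and 0 passed either over all genes or adjusted over the list alone. The smallest p were those of Egr2 (1.54-fold, 0.62 ± 0.24), Nr4a3 (0.39 ± 0.16), Arc (0.53 ± 0.24) and Sik1 (0.22 ± 0.10), which encode activity-induced transcription factors, a synaptic protein and a salt-inducible kinase. The list's median, relative to the control mean of the experiment, was 0.39 and 0.45 on ethanol replicate 2 of experiment 1 and ethanol replicate 1 of experiment 2, and -0.12, 0.14 and -0.03 on the other ethanol arrays. Leaving out ethanol replicate 2 of experiment 1 ended the call (median 0.08, camera adjusted p = 0.068), as did leaving out ethanol replicate 1 of experiment 2 (median 0.07, camera adjusted p = 0.0701). Without control replicate 1 of experiment 2 the median was 0.10 (camera adjusted p = 0.00575).

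**Figure D2:**
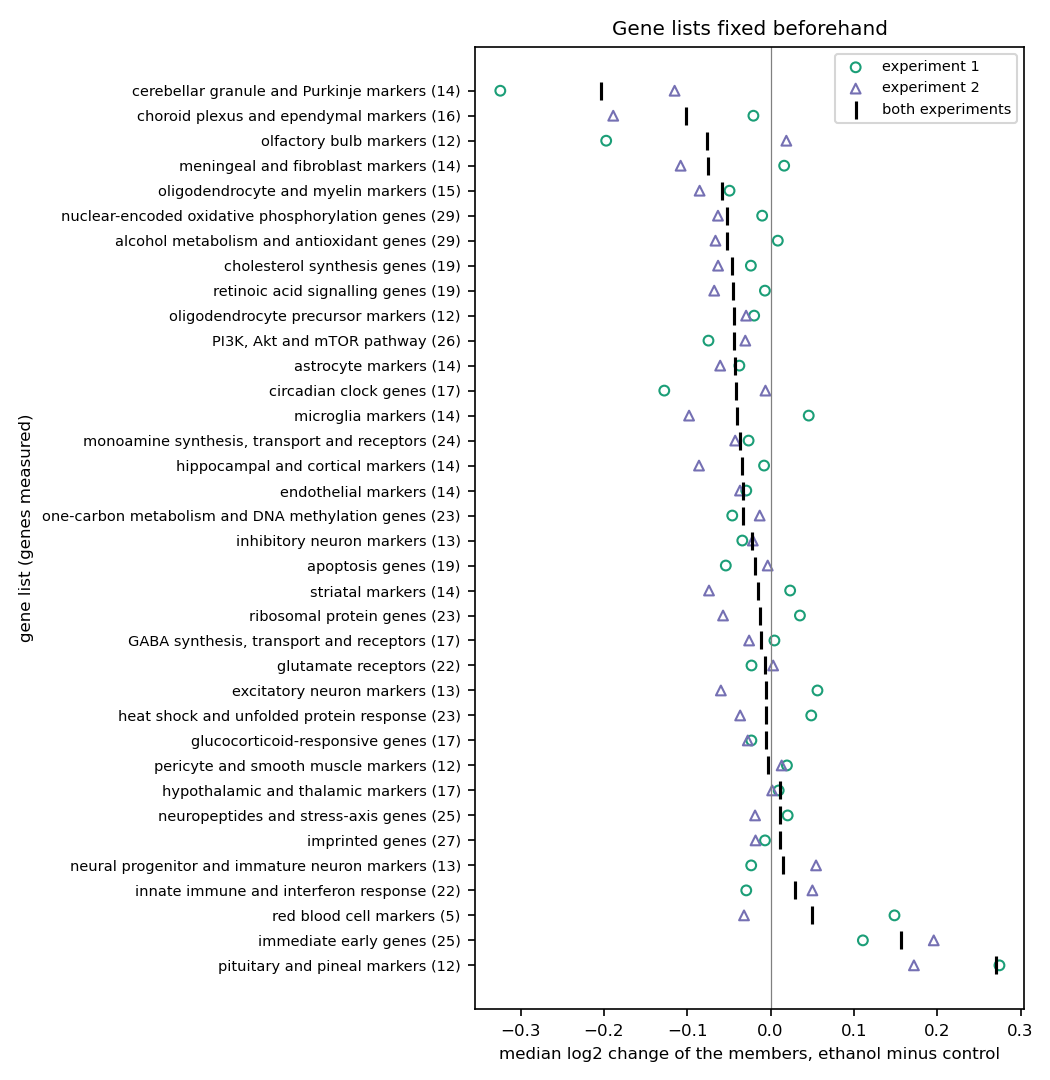
Median log2 difference between ethanol and control arrays (x axis) over the measured members of each of 36 gene lists (y axis, number measured in brackets), in experiment 1, in experiment 2 and over both. The cerebellar list lies lowest at -0.20 and the pituitary and pineal list highest at 0.27 over both experiments.

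No single gene passed the threshold over both experiments. limma called 0 of 21789 probe sets at adjusted p 0.05 (smallest adjusted p = 0.215), and an unmoderated linear model called 0. At an unadjusted p under 0.05 there were 2703 by limma (1029 higher and 1674 lower on the ethanol arrays) and 2422 by the unmoderated model, where chance alone gives about 1089. Of the 2703, 61.9% were lower. That share was 74.0% after quantile normalization, 87.4% with each array centred on its median and 93.5% among probe sets above the median level, but 49.7% over all probe sets, those without a gene name included. Array medians were higher on the ethanol arrays by 0.0274, so centring itself raises the share. The filter keeps the brighter probe sets, which were mostly lower. Only 98 of the 2703 differed by at least 1.2-fold (52 higher and 46 lower). Without ethanol replicate 2 of experiment 1 limma called 1 gene.

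The 12 lower genes were those with the smallest p under the naming rule, which required at least 1.2-fold and the same sign in both experiments. Several have a known function. Tmem229b, a transmembrane protein (probe set 10401160), was lower on 5 of 5 ethanol arrays (-0.27 ± 0.04, adjusted p = 0.215), and a further probe set of the same gene gave -0.21 ± 0.06. Mrpl42, a mitochondrial ribosomal protein, had the largest of these 12 differences (-0.43 ± 0.08, 1.35-fold). Itpkb, an inositol trisphosphate kinase (-0.26 ± 0.05), Pdcd10, which is mutated in familial cerebral cavernous malformations (-0.30 ± 0.06, and -0.13 ± 0.05 in its other probe set), Dkc1, the pseudouridine synthase dyskerin (-0.27 ± 0.05), Cd59a, an inhibitor of the complement membrane attack complex (-0.31 ± 0.06), and Fmod, the collagen-binding proteoglycan fibromodulin (-0.30 ± 0.06), were each lower on 5 of 5 ethanol arrays. So were Zadh2 (-0.28 ± 0.05), Klhl4 (-0.29 ± 0.05), Iqub (-0.28 ± 0.05), Tmem198b (-0.30 ± 0.05) and the choroid plexus channel Kcnj13. All 12 missed the threshold, each at an adjusted p of 0.215.

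The 12 higher genes taken by the same rule differed by 0.27 to 0.37 log2 units and missed the threshold at adjusted p of 0.215 or 0.306. They included the microRNA genes Mir34c (0.27 ± 0.05), Mir7b (0.27 ± 0.07) and Mir155 (0.30 ± 0.08), and Ghrhr. Vpreb1, a component of the pre-B-cell receptor (0.29 ± 0.06), Ang6, a ribonuclease of the angiogenin family (0.27 ± 0.07), and Tas2r118, a bitter taste receptor (0.28 ± 0.08), were higher on 5 of 5 ethanol arrays. Fam155a, a subunit of the sodium leak channel (0.29 ± 0.08), was higher on 4 of 5. The butyrophilin-like pseudogene Btnl5-ps (0.37 ± 0.10), Svs3a, a seminal vesicle protein (0.27 ± 0.07), and the hair-keratin-associated Krtap31-2 (0.35 ± 0.10) completed the set. Adamts9, a secreted metalloproteinase, was higher by 0.31 ± 0.06 in probe set 10546450, but its 5 other probe sets ranged from -0.13 to 0.04, and the other probe sets of Btnl5-ps (0.02 and 0.04) and Fam155a (-0.08) did not follow either.

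**Figure D3:**
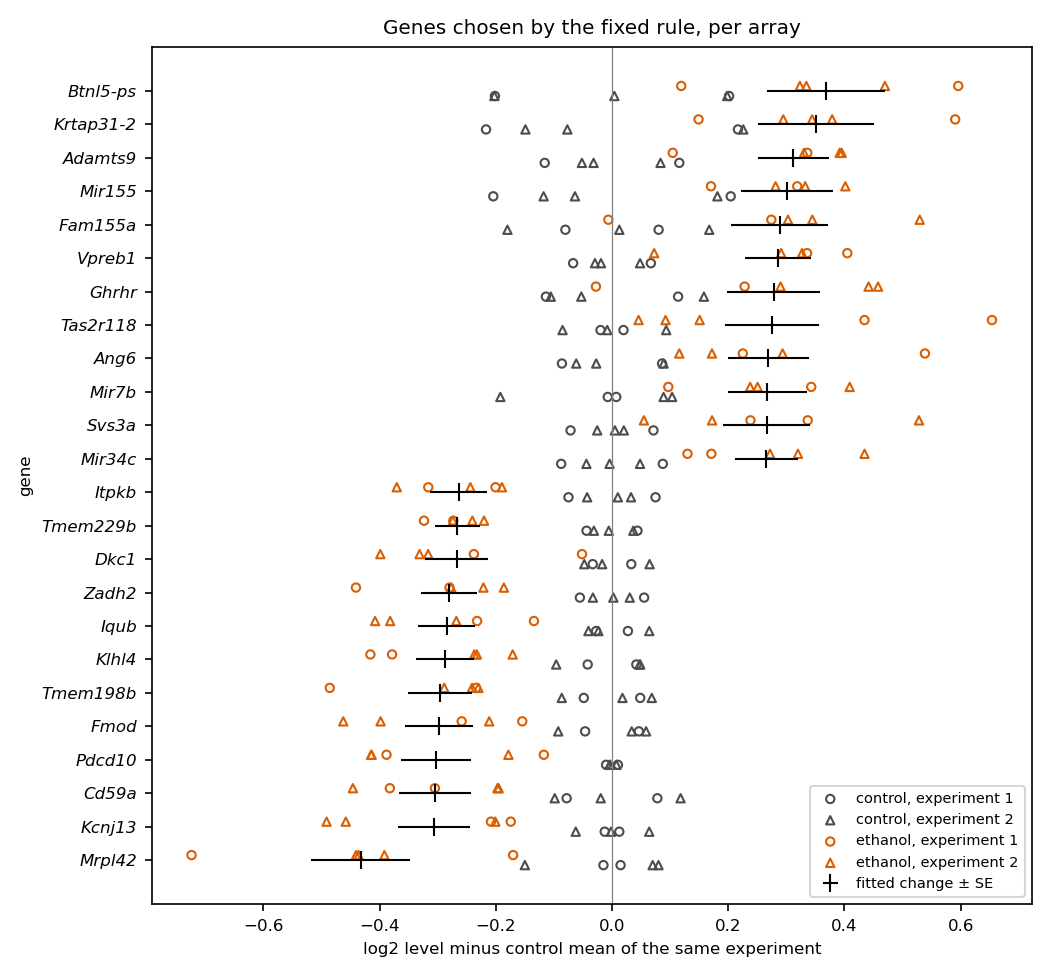
Log2 level of each of the 24 genes (y axis) on each array, minus the control mean of the same experiment (x axis), with the fitted difference and its standard error (5 ethanol and 5 control arrays). Ethanol arrays lie to the right for the 12 higher genes, except 1 array each for Fam155a and Ghrhr, and to the left for the 12 lower genes, and none of the 24 passed the threshold.

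The direction of a gene's difference varied with its signal level. Of the 25% of genes with the lowest mean level 79.3% were higher on the ethanol arrays, and at an unadjusted p under 0.05 there were 466 higher and 24 lower. Of the 25% with the highest level 22.5% were higher, with 28 higher and 571 lower at that p. The lower quartile of the array values was higher on the ethanol arrays by 0.0468 and the upper quartile differed by -0.0347, each at the smallest p the exact permutation test within experiments can give (two-sided p = 0.0167). After quantile normalization the lowest 25% held 119 higher and 125 lower genes at an unadjusted p under 0.05, while the other 3 groups, in order of level, held 175 and 531, 114 and 513, and 74 and 206. With the lower quartile of each array as a covariate, chosen after seeing the data, 659 genes in all had an unadjusted p under 0.05. The medians were then -0.02 for the cerebellar list (camera adjusted p = 0.589) and 0.16 for the pituitary list (0.155), which no longer passed, and -0.16 for the choroid plexus list (6.8e-06) and 0.14 for immediate early genes (0.0166), which did. That quartile was higher on each ethanol array than on each control of its experiment, so the covariate overlaps with treatment, and a call lost with it says little about the list. Among the named genes, Vpreb1, Mir34c and Svs3a lay at control means of 5.54 to 6.00 log2 units, and Itpkb and Cd59a at 9.43 to 9.91, but the lower gene Iqub lay at 5.89 and 5.97 and the higher pseudogene Btnl5-ps at 8.34 and 8.33.

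**Figure D4:**
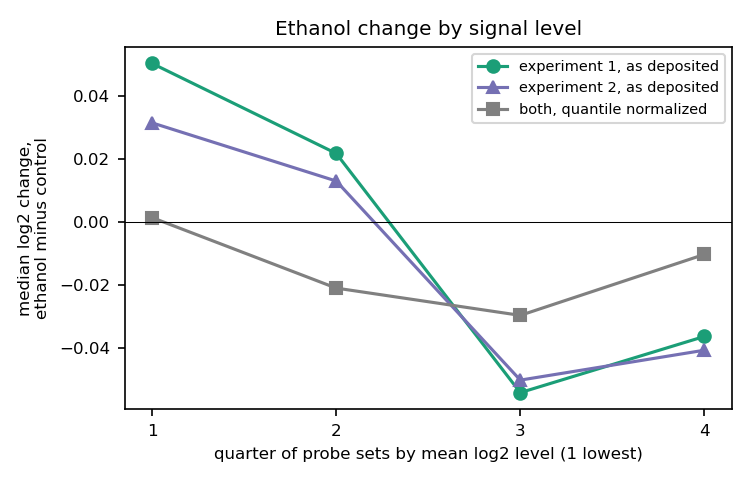
Median log2 difference between ethanol and control arrays (y axis) in 4 equal groups of the genes by mean log2 level (x axis), for each experiment as deposited and for both after quantile normalization. As deposited, the lowest group lies at 0.05 and 0.03 in experiments 1 and 2 and the highest at -0.04 in each.

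None of the other lists passed over both experiments by camera. Oligodendrocyte and myelin markers were lower in 13 of 15 (median -0.06, camera adjusted p = 0.0513), including Ermn (-0.17 ± 0.06) and Mog (-0.12 ± 0.05). Meningeal and fibroblast markers were lower in 13 of 14 (median -0.07, camera adjusted p = 0.0513), and Dcn, which encodes decorin (-0.19 ± 0.05), passed adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were lower in 24 of 29 (median -0.05, camera adjusted p = 0.0513). Astrocyte markers were lower in 11 of 14 (median -0.04, camera adjusted p = 0.0714) and microglia markers in 9 of 14 (median -0.04, camera adjusted p = 0.636). Genes of alcohol metabolism and antioxidant defence were lower in 22 of 29 (median -0.05, camera adjusted p = 0.0579), with Aldh1a1, a retinaldehyde dehydrogenase, at -0.14 ± 0.04. Genes of the phosphoinositide 3-kinase, Akt and mTOR pathway were lower in 20 of 26 (median -0.04, camera adjusted p = 0.0579), and Tnfrsf1a, the tumour necrosis factor receptor on the apoptosis list (-0.22 ± 0.05), passed adjusted over that list alone. Cholesterol synthesis genes were lower in 16 of 19 (median -0.05, camera adjusted p = 0.0579). The remaining lists had camera adjusted p from 0.155 (retinoic acid signalling genes, lower in 16 of 19) to 0.931 (heat shock genes). The sign of the median differed from that of the test for glucocorticoid-responsive genes, glutamate receptors, pericyte markers, and hypothalamic and thalamic markers, all at camera adjusted p of 0.615 or more.

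In experiment 1, with 2 arrays per treatment, cerebellar markers were the lowest group, with a median difference of -0.32, and Gabra6 differed by -0.45, Zic1 by -0.35 and Zic2 by -0.30. Pituitary and pineal markers were higher (median 0.27), Gh by 5.04 and Prl by 4.38 log2 units. Circadian clock genes were lower (median -0.13), including Dbp (-0.50) and Bhlhe41 (-0.25), as were olfactory bulb markers (median -0.20), including Pax6 (-0.37) and Th (-0.31), and genes of the phosphoinositide 3-kinase pathway (median -0.07). These 5 lists passed by camera (adjusted p from 1.9e-07 to 0.0347), and each had adjusted p = 0.941 with an estimated correlation. For single genes limma called 0 of 21789 (smallest adjusted p = 0.171), with 1951 at an unadjusted p under 0.05 (877 higher and 1074 lower). Fitted on the 4 arrays of this experiment alone, limma called 1, and without control replicate 1 there were 1126 at an unadjusted p under 0.05. Without ethanol replicate 1 it called 235, in a fit that assumes the lone remaining ethanol array to vary like the other groups.

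In experiment 2, with 3 arrays per treatment, choroid plexus and ependymal markers were the lowest group, with a median difference of -0.19, and Kcnj13 differed by -0.38, Kl by -0.37 and Otx2 by -0.35. Meningeal (median -0.11), microglia (-0.10), myelin (-0.09) and astrocyte markers (-0.06) were lower, as were cerebellar markers (-0.12), oxidative phosphorylation genes (-0.06), genes of alcohol metabolism (-0.07) and retinoic acid signalling genes (-0.07). Immediate early genes (median 0.20), pituitary markers (0.17) and innate immune and interferon genes (0.05) were higher. These 12 lists passed by camera (adjusted p from 1.9e-08 to 0.0301), and with an estimated correlation 0 passed, the smallest being adjusted p = 0.193 with an estimated correlation, for the choroid plexus and meningeal lists. For single genes limma called 0 of 21789 (smallest adjusted p = 0.149), with 2172 at an unadjusted p under 0.05 (824 higher and 1348 lower). limma called 3 with an intensity trend and robust prior and 2 with array weights, and 1 without control replicate 3.

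The ethanol difference was compared between the experiments by its interaction with experiment. Pde4d, a cyclic AMP phosphodiesterase, was lower on the ethanol arrays in experiment 1 (-0.47 ± 0.10) and higher in experiment 2 (0.30 ± 0.08), but its 2 other probe sets differed between the experiments by only -0.01 and -0.02. Kansl1, a chromatin regulator (-0.15 and 0.44, a difference of 0.59 against 0.14 in its other probe set), Cd46, a complement regulator (-0.34 and 0.16), Gpatch8 (-0.38 and 0.12, a difference of 0.50 against 0.06 to 0.45 in its 4 other probe sets) and the microRNA gene Mir138-2 (-0.31 and 0.36) had the same signs, and Ssna1, a microtubule-associated protein, the opposite ones (0.16 and -0.42). None passed the threshold (adjusted p = 0.443 to 0.598), and limma called 0 of 21789 (smallest adjusted p over all genes 0.269), with 1432 at an unadjusted p under 0.05 where chance gives about 1089. Without ethanol replicate 1 of experiment 1 it called 94, with 2692 at an unadjusted p under 0.05, and without control replicate 3 of experiment 2 it called 3. By camera 12 lists differed between the experiments, among them the choroid plexus list, lower in experiment 2 (adjusted p = 3.7e-04; adjusted p = 0.495 with an estimated correlation), and the cerebellar list, lower in experiment 1 (adjusted p = 0.00613; adjusted p = 0.6 with an estimated correlation).

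Across genes, the ethanol differences of the experiments were weakly related. Pearson's r was 0.223 and Spearman's rho 0.208 over 21789 probe sets, and 57.5% had the same sign. Among the 1951 with an unadjusted p under 0.05 in experiment 1 the same sign was found for 65.2%, and among the 2172 of experiment 2 for 64.0%. After quantile normalization r was 0.115. Without ethanol replicate 1 of experiment 1 it was 0.0745, without control replicate 1 of experiment 1 it was 0.0779, and without ethanol replicate 2 of experiment 2 it was 0.14. Of the 36 lists, 22 had a median of the same sign in both experiments, among them the 4 that passed over both. Those 4 were called on the same arrays, so their matching signs were nearly fixed in advance. The choroid plexus median was only -0.02 in experiment 1.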

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

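The test of an ethanol effect in every pool was chosen only after the result was seen.

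Gh, Prl and Cga were far higher on 3 ethanol arrays, which may reflect pituitary tissue in some brain pools. In a fit with their mean as a covariate, the 7 other pituitary genes measured had a median slope of 0.0396 per log2 unit, all positive (camera p = 2.1e-10, and p = 0.0046 with an estimated correlation), from 0.00689 for Pitx1, 0.0095 for Ghrhr and 0.0154 for Tbx19 to 0.114 for Fshb and 0.176 for Pomc. Of the 12 list members measured, 1 is on another list, and 0 had control means above the median of the gene probe sets. An excess as large as on those 3 ethanol arrays was not seen in every pool. Ethanol replicates 1 and 3 of experiment 2 had means of 6.91 and 6.95, against 6.87, 6.78 and 7.69 on their controls. They lay over 0.5 log2 units below the highest control but above the other controls. A smaller ethanol effect in every pool is therefore not excluded. An ethanol effect in some litters was not tested and stays open.

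Cerebellar and choroid plexus markers were lower on the ethanol arrays, and a smaller share of these tissues in the ethanol pools could give this. Further genes written down before their values were looked at were also lower: 14 of 15 in the second cerebellar list (median -0.17, camera p = 1.5e-06, and p = 0.126 with an estimated correlation). In the second choroid plexus list 13 of 17 were lower (median -0.09, camera p = 4.2e-04, and p = 0.0674 with an estimated correlation). The second lists mark the same tissues on the same arrays, so they cannot tell ethanol from another difference between the pools. They were not tested with exchanged treatment labels. These values do not separate a smaller share of tissue from lower transcription within it, and an effect of ethanol on either was not tested.

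Dim gene probe sets were mostly higher and bright ones mostly lower on the ethanol arrays, and among genes at an unadjusted p under 0.05 more were lower than higher, though over all probe sets 49.7% were lower. Higher background signal on the ethanol arrays may account for the dim probe sets. Of 3579 dim probe sets that the annotation does not list, 69.4% were higher (65.2% to 70.4% without each array in turn), but so were 54.8% of the 4235 unlisted probe sets above the median level, unlike the bright gene probe sets. A difference in the whole intensity distribution was tested by quantile normalization, after which the share lower among gene probe sets was 74.0%. This cannot decide the question, since the normalization itself moved the counts of lower genes. From the dimmest to the brightest group they went from 24 to 125, 246 to 531, 833 to 513 and 571 to 206. The excess is also absent over all probe sets. Processing dates are not used here, and an ethanol effect on many transcripts was not tested, so both stay open.

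Single arrays stood apart from the other 4 of their treatment in 5 of 82 groups of values tested, where chance gives about 4.1. These groups pool the levels of both experiments, whose means had been made equal per probe set, so the gaps between arrays of different experiments partly reflect that step. Ethanol experiment 1 replicate 1 had the lowest array median of the ethanol arrays (7.02, next 7.04, gap over range 0.820). Control experiment 1 replicate 1 had the highest upper quartile of the controls (9.05, next 8.998, gap over range 0.756). Vpreb1 was lowest on ethanol experiment 2 replicate 2 (6.07, next 6.27, gap over range 0.736), and Mir7b on control experiment 2 replicate 1 (6.94, next 7.16, gap over range 0.759). The mean of 12 olfactory mucosa genes was highest on control experiment 2 replicate 2 (8.40, next 6.18 in experiment 1, gap over range 0.730), and the next control of its own experiment had 5.62. Those 12 genes were chosen because they had been noticed in these data. Their outlier is therefore no independent test, though it is counted among the 5.

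The ethanol difference of 12 gene lists differed between the experiments by camera on the interaction. With an estimated correlation 0 did (smallest adjusted p = 0.495 with an estimated correlation). Cerebellar markers had medians of -0.32 in experiment 1 and -0.12 in experiment 2 (adjusted p = 0.00613), and circadian clock genes -0.13 and -0.01 (adjusted p = 0.00613). Olfactory bulb markers had -0.20 and 0.02 (adjusted p = 0.0365). Choroid plexus markers had -0.02 and -0.19 (adjusted p = 3.7e-04), meningeal markers 0.02 and -0.11 (adjusted p = 0.0365), and microglia markers 0.05 and -0.10 (adjusted p = 0.00582). Oxidative phosphorylation genes had -0.01 and -0.06 (adjusted p = 0.0249), genes of alcohol metabolism 0.01 and -0.07 (adjusted p = 0.0365), and innate immune genes -0.03 and 0.05 (adjusted p = 0.0399). Ribosomal protein genes had 0.04 and -0.06, striatal markers 0.02 and -0.07, and heat shock genes 0.05 and -0.04 (each adjusted p = 0.0249).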

How the results depend on the processing

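The alternatives with a covariate and the one without the 3 arrays of highest pituitary signal were chosen only after the result was seen, and the others were planned. All 586 values of the 24 named genes kept their direction, and 0 passed by limma (adjusted p 0.0509 to 0.999). These genes were chosen from the same data by size, p and sign in both experiments, so their direction was nearly fixed in advance. Of the values for single lists 792 kept their side of the threshold, 58 newly passed and 14 no longer did, and of the counts and correlations 163 stayed within their limits and 41 did not. Where no reason is given, the cause was not tested. Quantile normalization gave an agreement of 0.115. Probe sets above the median, fewer genes by construction, gave 0.134 and 1575, 1099, 1345 and 830 genes at an unadjusted p under 0.05 (both experiments, experiment 1, experiment 2 and their difference). All probe sets, a larger number tested, gave 3264 in experiment 2 and 2423 for the difference. An intensity trend with a robust prior gave 3 calls in experiment 2 and 11 lists. Array weights gave 2 calls and 3276 unadjusted in experiment 2, 1154 unadjusted in experiment 1 and 9 lists. Only the arrays of experiment 1 gave 1 call and 1061 unadjusted. An unadjusted p under 0.05 with at least 1.2-fold gave 98 genes. Camera with an estimated correlation and fry each gave 0 lists, and the mean over probe sets 7. Genes with an unadjusted p under 0.05 in experiment 1 had an agreement of 0.522. The mean of Gh, Prl and Cga as a covariate gave 1383 unadjusted and 8 lists, the lower quartile as a covariate 659 and 2, and leaving out the 3 arrays 11 lists. That last setting leaves experiment 1 without an ethanol array, so it compares 2 ethanol with 3 control arrays of experiment 2 and is no value over both experiments. By construction the first sets the mean difference of Gh, Prl and Cga to 0 and the last removes the arrays where they were highest. The lower quartile overlaps with treatment. Leaving out each array gave 0 to 1 calls over both experiments (1 without ethanol experiment 1 replicate 2) and 1841 to 3423 unadjusted. It gave 0 to 235 calls and 1126 to 2810 unadjusted in experiment 1, and 0 to 1 and 1516 to 2681 in experiment 2. For the difference it gave 0 to 94 and 1139 to 2692, for the agreement 0.0745 to 0.295, and 4 to 11 lists. The 235, 94, 2692 and 0.0745 came without ethanol experiment 1 replicate 1, which leaves an arm of 1 array assumed to vary like the other groups. Lists numbered 7 without ethanol experiment 1 replicate 2, 11 without control experiment 1 replicate 2 and 10 without control experiment 2 replicate 3. Same-numbered arrays had correlations of -0.146 to 0.230 in their deviations from the group means. With 2 or 3 arrays per group these deviations are tied together, so they cannot show whether replicate numbers pair the arrays. A block on replicate numbers gave 5 lists. Control means above the median of the gene probe sets were found for 0 of 12 pituitary and 13 of 14 cerebellar markers, and how signal over background limits the results was not tested.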

Other observations

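The test of the gap between dim and bright genes against other splits was chosen only after the result was seen, as were the olfactory mucosa genes.

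Within the second cerebellar list, Ppp1r17, a Purkinje cell phosphatase inhibitor, differed by -0.43 ± 0.12 log2 units between ethanol and control arrays. Tfap2b, a transcription factor, differed by -0.31 ± 0.08, and Barhl2 by -0.23 ± 0.08. None passed the threshold over all genes by limma. Within the second choroid plexus list, Cox8b differed by -0.20 ± 0.05, Slc31a1, a copper transporter, by -0.17 ± 0.04, and Trpv4, a cation channel, by -0.13 ± 0.04. None of these passed either. All of these genes are already counted in the results of the second lists and add no separate evidence. They were named after their values were seen.

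Olfactory mucosa genes, noticed in the data, had a mean of 8.40 log2 units on control experiment 2 replicate 2 and of 5.35 to 6.90 on the other 5 arrays of that experiment. Bpifb9b reached 10.0 on that array. In 10 further olfactory mucosa genes, 7 had a positive slope on that mean (median 0.0207, camera p = 0.00147, and p = 0.0886 with an estimated correlation).

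Treatment labels were exchanged within experiments to give 60 splits of the 10 arrays, the real one included. The 2703 genes at an unadjusted p under 0.05 were reached or exceeded in 2 of 60 splits, a share under 0.05. The highest other split gave 3362, with replicate 2 of ethanol and control exchanged in experiment 1. This was 1 of several such tests, made without adjustment, and an exchanged split gave more genes, so chance is not taken as excluded. The gap of 0.0801 log2 units between the median differences of the 25% dimmest and the 25% brightest genes was reached in 1 of 60 (highest other 0.0788), but as the measure was chosen after the pattern was seen and the margin is small, chance is not taken as excluded. The 0 calls by limma were reached in 60 of 60 (highest other 1). The agreement of 0.223 was reached in 3 of 60 (highest other 0.279), and chance cannot be excluded. In experiment 2 the 10 splits are too few for a share under 0.05, with 2172 genes in the real split, which was the largest (1 of 10), and 1409 in the highest other.

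For the gene lists chance cannot be excluded. The 4 lists past the threshold by camera were reached in 42 of 60 splits, and the highest other split had 13, so lists also passed at the preset correlation of 0.01 when labels were exchanged. A camera p as small as the real one was reached in 15 splits for cerebellar markers (-log10 p 6.51, highest other 11.7) and in 6 for pituitary markers (5.85 and 8.59). It was reached in 7 for choroid plexus markers (5.50 and 12.3) and in 22 for immediate early genes (4.57 and 28.8).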
